A study of Mus musculus with 6 samples.

How the data were processed

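RNA was extracted from dissected mouse embryo heads at embryonic day 8.5, polyA-selected and made into stranded paired-end libraries that were sequenced on a HiSeq 2500, per the labels' protocols. There were 6 libraries, 2 for each of 3 genotypes at Prdm15, and the protocol speaks of 2 heads per genotype. The labels do not say more on litters or batches, so p-values measure the spread between these libraries only.

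Per the submitters' processing notes, bcl2fastq 2.17, FastQC 0.11.2, Trim Galore 0.4.0, cutadapt 1.8, TopHat2 2.0.11, HTSeq 0.6.1p2 and edgeR 3.8.6 were used, with mm10 as the genome build. The annotation and the strand setting of the counter are not given in the sources used here, so genes that overlap on either strand and close paralogs, such as globin and granzyme genes, are uncertain. The authors deposited raw counts per gene for each library, 24062 gene symbols and 5 summary lines that were left out of library sizes and tests. Of all read pairs in a file, 8.93% to 10.5% lay in no feature, 1.04% to 1.08% were ambiguous and 12.7% to 14.5% had no unique alignment. A table of the whole series, deposited by the authors, gives RPKM values per library under the sample titles, a log2 fold change and log2 average CPM of the authors, a likelihood ratio score, and p-values with false discovery rates for mutant against wild type and for a comparison over all genotypes whose coding is not given. The second comparison was not analysed here.

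The count files attached to wild-type replicate 2 and mutant replicate 1 bear each other's titles. The design fixed before the data were examined was to use title-named columns if the series table held raw counts, and otherwise to keep each file under the sample it is attached to, and to test the exchange of the 2 files beside it. The table held RPKM, so the attached files are the planned main result. The RPKM columns reproduce zeros and ratios of the exchanged files, and so every step was also run with the 2 files assigned by title, a full set of fits added after the data were seen. The report leads with the assignment by title and prints the planned one beside it; no library was assigned by the level of any gene. The ratio of count to RPKM, divided by that of wild-type replicate 1 so that gene length cancels, was compared at genes with more than 50 counts in both libraries, with a tolerance of 0.1%; wild-type replicate 1 itself was matched by its zeros alone.

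Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test (glmQLFit, glmQLFTest), with TMM normalization, filterByExpr by group, all 6 libraries in 1 fit with 3 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05; 15187 genes were tested. All adjusted p of single genes come from this test unless another tool is named. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values of single genes use TMM library sizes, while sums over lists and the 3-read floors use library totals. The common biological coefficient of variation was 0.182 by title and 0.387 with the files as attached. Where a group held 0 reads, the fold was computed against 3 reads over the group's summed library size; 3 reads equal 0.0742 to 0.102 CPM in a single library, and such floors cover counting error only.

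Gene lists, 34 in number, were fixed before the data were examined, with 8 entries whose symbol is not in the count files. They cover brain regions, neural and crest lineages, signalling pathways, other tissues that a head dissection can carry (yolk sac visceral endoderm, heart, trunk, erythroid, endothelium), stress, sex and RNA checks. Lists of at least 5 tested genes were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. They were also tested by fry for movement in 1 direction. All p-values were adjusted over the lists within a contrast. Camera with an estimated correlation rests on the 3 residual degrees of freedom and has little power here. Named genes follow a rule fixed before the data were examined: Prdm15 and Otx2; among genes that passed with a mean of at least 1 CPM and no overlap between the 2 groups, the 12 largest changes in each direction for mutant against wild type and 6 for each other contrast; up to 4 members with the smallest p of each list described, here those that passed camera in mutant against wild type; and where no gene passed, the 5 smallest p in each direction. Predicted genes were replaced by the next. Of the largest changes, 1 in each direction is not used here. Gene positions and current names come from GENCODE M21 on GRCm38, the assembly of mm10.

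The fits were tested on simulated counts of 15187 genes of which 100 changed 2-fold and 100 changed 4-fold in mutant libraries. With the spread of the libraries by title, mutant against wild type recovered 72% and 80% of them, with 16 false among 168 calls; with that of the files as attached it recovered 1% and 35%, with 5 false among 41. In mutant against heterozygous the recovery was 70% and 78% by title, with 20 false among 168 calls.

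Alternatives planned were the exchange of the 2 files, leaving both out, RLE size factors, library totals, no low-count filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, edgeR's likelihood ratio and exact tests, limma-voom, fits of 2 groups alone, sex-linked markers left out and leaving out each library in turn. Added after the data were seen were the same set by title, a term for libraries with high Xist counts, scaling to the neural progenitor list, leaving out markers of 4 other tissues, and limma on log2(RPKM + 0.1) of the authors' columns, a scale that understates changes of low genes. Overlaps of calls were set beside 20 simulations of unchanged groups. All fold changes are changes in relative abundance, so a tissue present in some libraries lowers the share of every other transcript there.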

Results

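PolyA-selected RNA was sequenced from mouse embryo heads on a C57BL/6 background at embryonic day 8.5, the stage at which the anterior neural plate is being patterned into forebrain, midbrain and hindbrain. The embryos carried 0, 1 or 2 copies of tm1a, a knockout-first insertion allele of Prdm15, a zinc finger gene of the PRDM family. Each genotype, wild type, heterozygous and mutant, had 2 libraries. Reads assigned to genes numbered 40439234 and 34656271 in the wild-type libraries by title, 31236970 and 29570459 in the heterozygous ones and 39068327 and 29412227 in the mutant ones. The series title names Otx2 and forebrain development, so the comparisons address what changes in the head when Prdm15 carries this allele.

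For 1 wild-type and 1 mutant sample the title and the name of the attached count file disagreed, each file bearing the other sample's title. The deposited RPKM table has a column for each title. The file attached to wild-type replicate 2 had its zeros at the genes of the column titled mutant replicate 1 (0 genes differed), and for 100% of the genes compared the ratio of count to RPKM, divided by that of the same gene in wild-type replicate 1 so that gene length cancels, lay within 0.1% of 1 constant. Against the column of its own sample's title 1646 genes differed in zero status. The file attached to mutant replicate 1 matched the column titled wild-type replicate 2 in the same way, with 0 genes differing, and the other 4 files matched their own columns. Values below are given first by title, the assignment under which title, genotype label, table column and file name agree, and the value with the files as attached stands beside the main results. That order was chosen after the table had been read. With the files as attached, edgeR's quasi-likelihood test passed 0 genes in mutant against wild type, 0 in heterozygous against wild type and 0 in mutant against heterozygous, with 318, 48 and 422 genes at an unadjusted p under 0.05. DESeq2 passed 86, 1 and 98 genes there, the likelihood ratio test 114, 1 and 140, the exact test 66, 1 and 165, and limma-voom 0, 0 and 0.

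Spearman's correlation of log2 CPM across genes, which are not independent replicates, was 0.986 between the wild-type libraries, 0.992 between the mutant ones and 0.993 between the heterozygous ones by title. With the files as attached it was 0.948 within wild type and 0.951 within mutant. Dividing the 4 wild-type and mutant files 2 against 2 gave 4654 genes along the titles, 0 along the attached samples and 0 for the remaining division, with 6654, 318 and 69 genes at an unadjusted p under 0.05.

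Prdm15 (chromosome 16, 97791467 to 97851850, minus strand, GRCm38) was counted at 35.2 and 32.6 CPM in the wild-type libraries, 28.3 and 31.8 in the heterozygous and 26.6 and 32 in the mutant libraries by title. Its log2 fold change was -0.21 (SE 0.12) in mutant against wild type (adjusted p = 0.221), -0.17 (SE 0.12) in heterozygous against wild type (adjusted p = 0.422) and -0.04 (SE 0.12) in mutant against heterozygous (adjusted p = 0.876). With the files as attached the mutant value was 0.07 (SE 0.17, adjusted p = 1). None of these differences passed the test. Scaled to the neural progenitor list, Prdm15 passed as higher, at 0.59 (adjusted p = 0.00897) in mutant against wild type and 0.50 (adjusted p = 0.0374) in mutant against heterozygous. That scaling moves the median of all genes by 0.81 and 0.54, so relative to all genes Prdm15 was not higher. Whole-gene counts of an allele that inserts a cassette into a transcribed gene do not separate normal from altered transcripts, so Prdm15 did not check the genotype labels under either assignment.

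Otx2 (chromosome 14, 48657677 to 48673819, minus strand), a homeobox gene required for forebrain and midbrain formation, was lower in both mutant libraries than in every other library by title. It stood at 97.4 ± 16 CPM in wild type, 73.7 ± 2.51 in heterozygous and 33.7 ± 12.5 in mutant libraries (SD, n = 2 each). The mutant against wild-type log2 fold change was -1.53 (SE 0.25), adjusted p = 0.00964. In heterozygous against wild-type libraries it was -0.40 (SE 0.25), adjusted p = 0.375, and in mutant against heterozygous -1.12 (SE 0.25), adjusted p = 0.103; neither passed. With the files as attached the mutant libraries stood at 86.1 and 24.9 CPM, and the log2 fold change was -0.45 (SE 0.71, adjusted p = 1). Scaled to the neural progenitor list, the value by title was -0.69 (adjusted p = 0.0357). In the authors' deposited table the Otx2 log2 fold change, mutant against wild type, is -1.54 with a false discovery rate of 1.32e-11, and that of Prdm15 is -0.22 with a rate of 0.579. That table gives a likelihood ratio score, so its rates are not those of the quasi-likelihood test. The likelihood ratio test here gave Otx2 an adjusted p of 3.31e-07 by title.

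**Figure D1:**
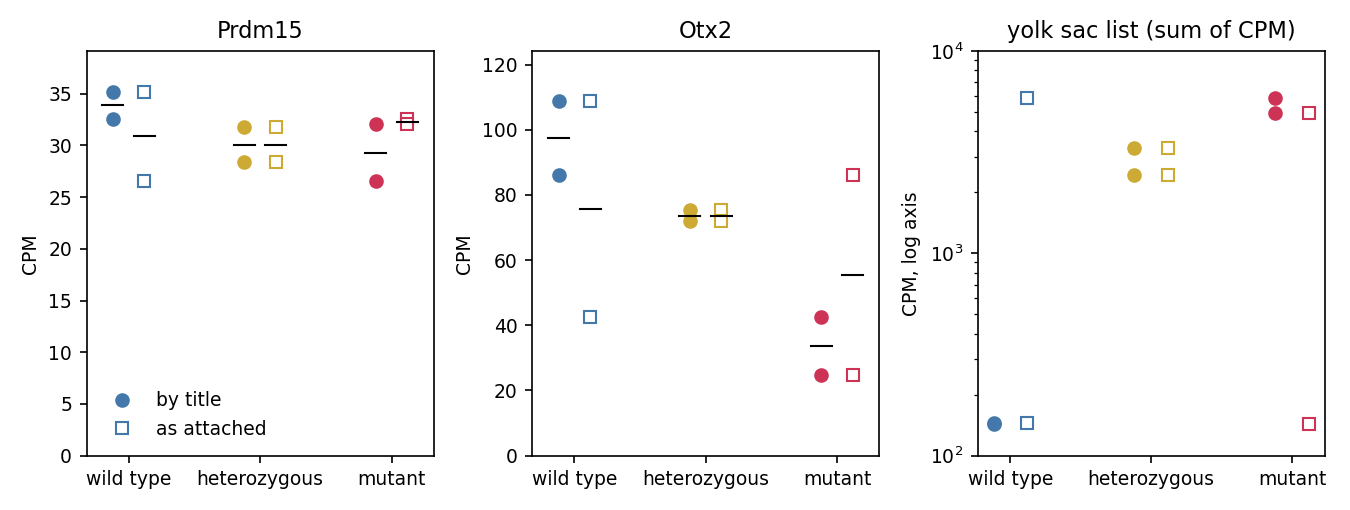
CPM of Prdm15, of Otx2 and summed over the 18 genes of the yolk sac visceral endoderm list (log axis) in each of the 6 libraries, filled circles by title and open squares with the files as attached. Black bars in the first 2 panels are means of 2 libraries. By title, Otx2 lay at 86.1 CPM or above in wild-type and at 42.5 CPM or below in mutant libraries. The yolk sac sum, which uses library totals, was 146 and 143 CPM in wild-type but at least 2444 CPM in every heterozygous and mutant library.

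The first comparison asks what differs between mutant and wild-type heads. By title, 18 of 22 forebrain genes were lower in mutant heads, and 18 of 18 yolk sac visceral endoderm genes and 16 of 17 heart genes higher. As lists these did not pass with an estimated correlation (adjusted p = 0.341, 0.227 and 0.495 with an estimated correlation). Of 15187 genes tested, 4654 passed, 2594 higher and 2060 lower in mutant libraries, and 1216 and 605 of these changed by more than 2-fold. In the authors' deposited table the genes with a false discovery rate under 0.05 number 3441 (2102 higher, 1339 lower), and 3089 of them passed here by title. Across genes its fold changes had a Spearman correlation of 0.999993 with those by title and -0.155 with those as attached. The count rests on how the libraries are assigned (0 as attached). It was 1997 to 4265 on leaving out single libraries and 2500 with a term for high Xist counts, as both mutant libraries were female and 1 wild-type library male. Scaling the libraries to the neural progenitor list moved the median of all genes by 0.81 on the log2 scale and gave 10902 higher and 355 lower genes in place of 2594 and 2060. Of the 78 genes picked for this comparison by the naming rule all but Prdm15 passed by title; as attached 0 passed, and 44 of the other 77 had the other sign.

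Several apolipoprotein genes were among the largest increases. Apoa4 was at 0 and 0.114 CPM in wild-type and 184 and 147 CPM in mutant libraries, and Afp, alpha-fetoprotein, at 0.169 and 0.683 against 484 and 365 (log2 fold change 10.01, SE 0.36). Apoc2 rose by 10.44 (SE 0.49) and Apoa1 by 10.24 (SE 0.49) on the log2 scale, reaching 760 and 614 CPM. The glucose transporter Slc2a2 was at 58.8 and 50 CPM in mutant libraries, against 3 reads in both wild-type libraries together. For 6 genes the wild-type libraries held 0 reads, and the fold is a lower bound set by 3 reads over the group. Spp2 was at least 431-fold higher, A1cf at least 123-fold, Mbl2 at least 122-fold, Apoc3 at least 108-fold, Cidec at least 98.3-fold and Ifi27l2b at least 97.6-fold. The adjusted p of these 11 genes lay between 0.000247 and 0.0017 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 18 members of the yolk sac visceral endoderm list rose (median log2 fold change 8.54, camera adjusted p = 9.27e-120, adjusted p = 0.227 with an estimated correlation, 18 higher and 0 lower over the list alone). Hnf4a, a transcription factor of endoderm and liver, rose by 8.46 (SE 0.29). The summed list was 146 and 143 CPM in wild-type libraries and 5838 and 4932 CPM in mutant libraries.

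Among the largest decreases, the eye and forebrain homeobox genes Six6 and Rax changed by -5.09 (SE 0.91) and -4.88 (SE 0.65) on the log2 scale. The neural crest regulators Sox10 (104 and 129 CPM to 1.65 and 1.09 CPM) and Tfap2b (-5.51, SE 1.07) fell, as did Rmst, a noncoding RNA of neural tissue, at -5.51 (SE 0.90). Fut10, of the fucosyltransferase family, went from 40.3 and 41.7 CPM to 0.186 and 0.375 CPM, a log2 fold change of -7.22 (SE 0.21), and Cntnap2, a neurexin-related adhesion gene, from 28.7 and 20.2 to 0.16 and 0.238 CPM (-6.94, SE 0.29). Cecr6 (-5.86, SE 0.41), BC024139 (-5.24, SE 0.76) and Mmrn1 (-4.62, SE 0.71) fell too, and so did the embryonic globin gene Hbb-y (-5.34, SE 1.54, adjusted p = 0.0475), whose reads can be shared with related globin genes. The adjusted p of the other 10 lay between 0.000207 and 0.0151.

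Of the 22 forebrain genes, 18 fell, 1 rose and 3 did not pass (median log2 fold change -2.37, camera adjusted p = 4.13e-08, adjusted p = 0.341 with an estimated correlation, 1 higher and 21 lower over the list alone). Besides Rax and Otx2, the members with the smallest p were Fezf2, at -2.45 (SE 0.28), and the Wnt antagonist gene Sfrp2, at -0.96 (SE 0.15). Of the 14 midbrain and isthmus genes 8 fell and 0 rose (median log2 fold change -1.80, camera adjusted p = 0.000949, adjusted p = 0.341 with an estimated correlation, 0 higher and 9 lower over the list alone). Pax5 was at -3.16 (SE 0.41), En2 at -4.26 (SE 0.80), Pax8 at -2.35 (SE 0.41) and Lmx1b at -0.96 (SE 0.16). Of the 16 Otx2 partners and downstream genes, 8 fell and 2 rose (median log2 fold change -1.22, camera adjusted p = 0.0206, adjusted p = 0.495 with an estimated correlation, 3 higher and 10 lower over the list alone). Lhx2 changed by -2.18 (SE 0.38), while Lhx1, a gene of the axial mesendoderm as well, rose by 5.08 (SE 0.67); this list shares Rax, Lhx2 and others with the forebrain list. The mutant libraries in which these genes were low had high yolk sac sums (5838 and 4932 CPM). Heterozygous libraries had high sums as well (3299 and 2444 CPM). In them 0 of 22 forebrain genes passed as lower, with a median log2 fold change of -0.60 against wild type.

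Pan-neural genes moved less. In the neural progenitor list 10 of 17 fell and 1 rose (median log2 fold change -0.69, camera adjusted p = 0.000627, adjusted p = 0.341 with an estimated correlation, 2 higher and 12 lower over the list alone). Sox1 changed by -0.69 (SE 0.06), Sox2 by -0.78 (SE 0.11) and Msi1 by -0.49 (SE 0.06). Vim, an intermediate filament gene of many embryonic tissues, rose by 1.08 (SE 0.13). Sox2 lies within the transcribed region of Sox2ot. Scaled to this list, Sox1, Sox2 and Msi1 here and Sox11 and Axin2 below changed sign, and none did relative to the shift of 0.81 in all genes. Of 14 neuronal differentiation genes 9 fell and 0 rose (median log2 fold change -1.13, camera adjusted p = 0.000351, adjusted p = 0.341 with an estimated correlation, 1 higher and 9 lower over the list alone). Examples were Neurog2, a proneural factor, at -2.87 (SE 0.49), Tubb3, neuronal tubulin, at -1.44 (SE 0.21), Stmn2 at -1.28 (SE 0.12) and Sox11 at -0.64 (SE 0.08). Of 18 neural crest genes 11 fell and 1, Snai2, rose by 1.21 (SE 0.19) (median log2 fold change -1.31, camera adjusted p = 2.89e-05, adjusted p = 0.491 with an estimated correlation, 1 higher and 14 lower over the list alone). Erbb3 changed by -1.44 (SE 0.22), Tfap2a by -1.04 (SE 0.17) and Cdh6 by -0.99 (SE 0.16). These falls, too, were in mutant libraries with high yolk sac, heart and trunk sums. Heterozygous libraries had high yolk sac (3299 and 2444 CPM) and heart sums (2075 and 3240 CPM) as well. In them 0 of 17 progenitor, 1 of 14 neuronal and 1 of 18 crest genes passed as lower. The list medians there were -0.12, -0.45 and -0.79.

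Among signalling lists, Notch pathway genes fell in 6 of 18 cases and rose in 1 (median log2 fold change -0.28, camera adjusted p = 0.00883, adjusted p = 0.362 with an estimated correlation, 1 higher and 6 lower over the list alone). Notch3 fell from 177 and 192 CPM to 54.3 and 41.3 CPM (-1.95, SE 0.13), and Rbpj, the DNA-binding partner of cleaved Notch receptors, changed by -0.81 (SE 0.06), as did the ligand gene Jag1 by -0.95 (SE 0.14) and Mfng by -1.77 (SE 0.21). Of 21 canonical Wnt targets and modulators 10 fell and 2 rose (median log2 fold change -0.38, camera adjusted p = 0.0184, adjusted p = 0.341 with an estimated correlation, 2 higher and 10 lower over the list alone). The R-spondin genes, which encode secreted Wnt enhancers, moved apart. Rspo1 (-2.42, SE 0.42) and Rspo2 (-3.25, SE 0.38) fell and Rspo3 (2.72, SE 0.26) rose. The Wnt target Axin2 changed by -0.64 (SE 0.09). Of 18 BMP targets and ligands 13 rose and 2 fell (median log2 fold change 0.91, camera adjusted p = 1.96e-06, adjusted p = 0.341 with an estimated correlation, 13 higher and 3 lower over the list alone). Hand1, which the heart list also holds, rose by 3.20 (SE 0.30), Tbx3 by 2.32 (SE 0.19) and Bmp4 by 2.07 (SE 0.22). In the same mutant libraries the yolk sac sums were 5838 and 4932 CPM against 146 and 143, and the heart sums 2501 and 1390 CPM against 316 and 115. Heterozygous libraries had yolk sac sums of 3299 and 2444 CPM and heart sums of 2075 and 3240 CPM. In them 0 of 18 Notch and 0 of 21 Wnt genes passed as lower, and 9 of 18 BMP genes as higher.

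Several lists of tissues outside the brain passed camera as higher. In the heart list 16 of 17 rose (median log2 fold change 3.51, camera adjusted p = 4.89e-07, adjusted p = 0.495 with an estimated correlation, 17 higher and 0 lower over the list alone). Gata4 rose by 4.79 (SE 0.56), Tbx20 by 3.70 (SE 0.60) and Nkx2-5 by 2.51 (SE 0.40). The summed list was 316 and 115 CPM in wild-type and 2501 and 1390 CPM in mutant libraries. In the trunk and tailbud list 9 of 18 rose and 0 fell (median log2 fold change 3.11, camera adjusted p = 4.76e-05, adjusted p = 0.341 with an estimated correlation, 14 higher and 0 lower over the list alone). The caudal gene Cdx2 rose by 6.32 (SE 0.82), as did the Hox genes Hoxb5 at 4.32 (SE 0.57), Hoxb6 at 4.72 (SE 0.33) and Hoxb8 at 3.78 (SE 0.41). Of 15 foregut endoderm genes 8 rose and 2 fell (median log2 fold change 0.60, camera adjusted p = 0.0007, adjusted p = 0.341 with an estimated correlation, 9 higher and 3 lower over the list alone). Foxa3 (4.55, SE 0.30), Gata6 (3.43, SE 0.39), Cpn1 (3.08, SE 0.36) and Cldn6 (1.34, SE 0.09) rose. The early epiblast list had 5 of 16 higher and 0 lower (median log2 fold change 1.00, camera adjusted p = 0.00188, adjusted p = 0.495 with an estimated correlation, 5 higher and 0 lower over the list alone). Higher members were Tfcp2l1 at 4.72 (SE 0.27), L1td1 at 3.84 (SE 0.27), Pou5f1 at 3.55 (SE 0.78) and Fgf5 at 2.41 (SE 0.50). Head mesenchyme genes rose in 8 of 16 cases and fell in 0 (median log2 fold change 0.45, camera adjusted p = 0.0184, adjusted p = 0.341 with an estimated correlation, 9 higher and 1 lower over the list alone). Pdgfra was at 1.20 (SE 0.07), Alx1 at 1.04 (SE 0.16), Prrx1 at 0.45 (SE 0.07) and Prrx2 at 0.45 (SE 0.08). With the correlation between genes estimated from the data, none of the 15 lists that passed camera with its preset correlation of 0.01 passed. That form of the test rests on 3 residual degrees of freedom and has little power here. Even the yolk sac list, with 18 of 18 members higher, did not pass it (adjusted p = 0.227). Fry passed 15 lists (smallest adjusted p = 0.00973).

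The other 19 lists did not pass camera in mutant against wild type, though single members did. The list medians on the log2 scale, with members higher and lower, were -0.22 for the hedgehog pathway (3 and 8 of 18), 1.01 for hindbrain genes (5 and 3 of 16) and -0.08 for genes mutated in holoprosencephaly (1 and 3 of 18). The median was 0.02 for the Wnt planar cell polarity pathway (4 and 6 of 21), 0.62 for the retinoic acid pathway (9 and 4 of 17) and 0.60 for the head organizer and axial mesendoderm (6 and 2 of 19). Surface ectoderm and placodes had -0.24 (3 and 6 of 18), FGF feedback genes 0.06 (5 and 7 of 18) and the PRDM family -0.20 (3 and 4 of 16). Hypoxia and glycolysis genes had a median of -0.32 (2 and 8 of 20), and cholesterol biosynthesis -0.15 (2 and 7 of 18). The integrated stress response had 0.25 (4 and 2 of 16), p53 targets 0.19 (1 and 1 of 20), the cell cycle -0.06 (1 and 3 of 20) and endothelium 0.19 (2 and 0 of 16). Primitive erythroid genes had a median of -2.01 (0 and 1 of 11), immediate-early genes 0.32 (2 and 0 of 18) and histone genes 0.21 (0 and 0 of 5). Of the 6 sex-linked genes 1 passed, Tsix, higher in mutant libraries at under 1 CPM; it overlaps Xist on the other strand. The sign of the median differed from that of the camera test for the PRDM family, FGF feedback and planar cell polarity lists. It differed from that of the mean for the integrated stress response (-0.05), FGF feedback (-0.05) and holoprosencephaly genes (0.52).

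**Figure D2:**
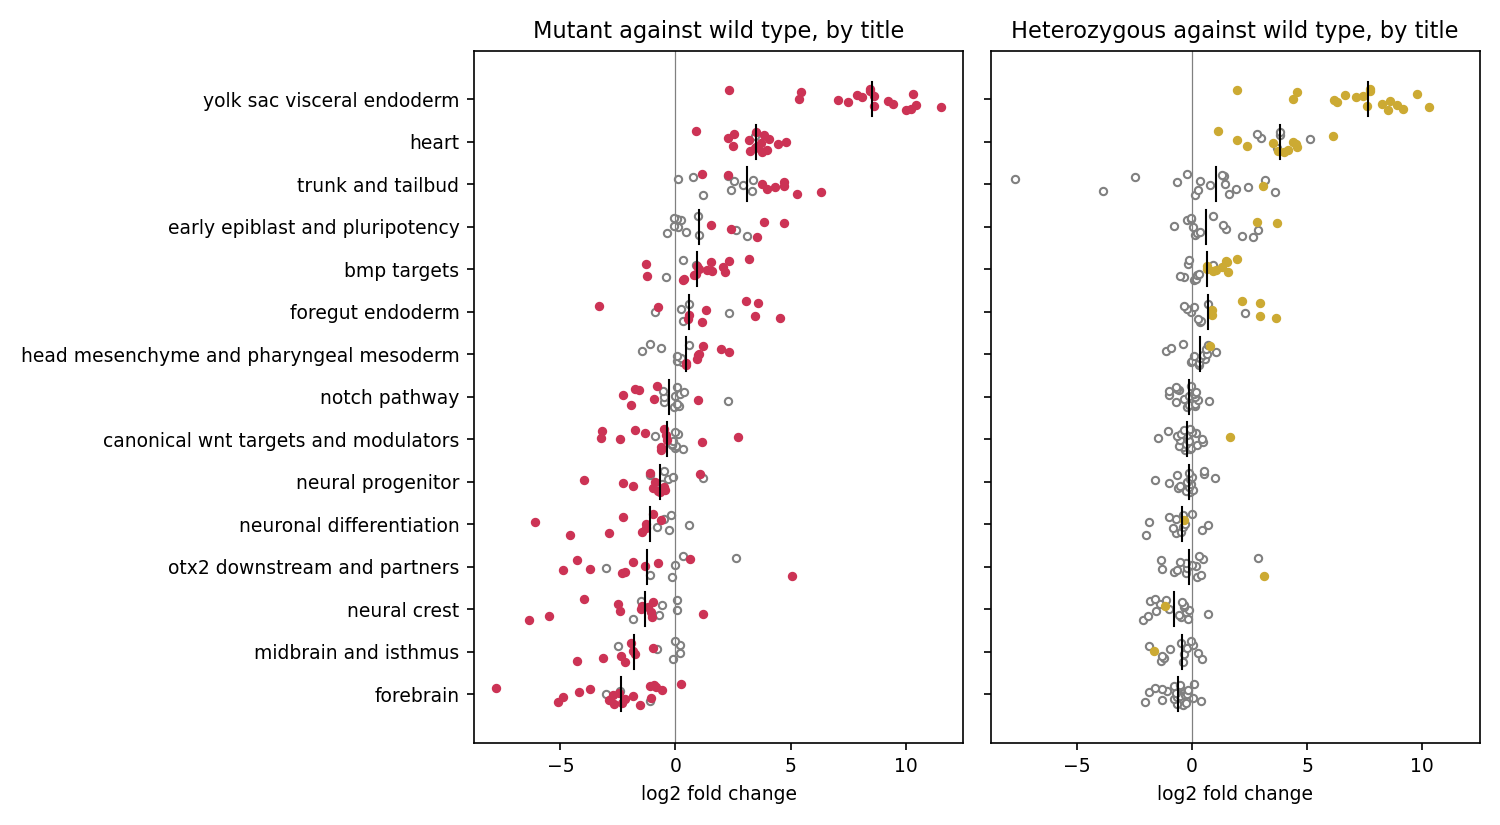
Log2 fold change of each tested member (x axis) of the 15 gene lists that passed camera in mutant against wild type (y axis), by title, for mutant (left) and heterozygous (right) against wild-type libraries. Filled points passed the test over all genes, open points did not, and black bars are list medians. The yolk sac list lies to the right in both panels (medians 8.54 and 7.65), while the forebrain median is -2.37 on the left and -0.60 on the right. Scaling to the neural progenitor list moves all points to the right, by 0.81 in the median gene on the left and 0.26 on the right.

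The second comparison asks what 1 copy of the allele does. By title, 18 of 18 yolk sac and 11 of 17 heart genes were higher in heterozygous heads, while none of the 22 forebrain genes passed. As lists the first 2 did not pass with an estimated correlation (adjusted p = 0.101 and 0.578 with an estimated correlation). Of 15187 genes 997 passed, 916 higher and 81 lower in heterozygous libraries, and 0 passed with the files as attached. Apoa4 stood at 76.4 and 65 CPM and Slc2a2 at 43.1 and 31.1 CPM against at most 4 reads in both wild-type libraries together. Against wild-type libraries with 0 reads, Spp2 was at least 103-fold, A1cf at least 73.7-fold and Ugt2b34, a glucuronosyltransferase gene, at least 60.5-fold higher. The largest decreases were in Aldh1a3, a retinoic acid synthesis gene of the eye and nasal region, at -2.61 (SE 0.47), Krt23 at -1.80 (SE 0.30), and Dmrta1 at -1.80 (SE 0.35). Fgf17, a growth factor gene of the isthmus, was at -1.67 (SE 0.35), Fam212a at -1.37 (SE 0.24) and St8sia4 at -1.26 (SE 0.25). The adjusted p of these 6 lay between 0.0277 and 0.0493. Without heterozygous replicate 1 the count was 313, without wild-type replicate 1 638 and without wild-type replicate 2 634, and with a term for libraries with high Xist counts 516 passed, among them 424 of the 916 higher and 4 of the 81 lower genes. DESeq2 passed 1890 genes, 1416 higher and 474 lower, in place of 916 and 81.

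All 18 yolk sac genes rose in heterozygous libraries (median log2 fold change 7.65, camera adjusted p = 7.57e-206, adjusted p = 0.101 with an estimated correlation, 18 higher and 0 lower over the list alone), and the summed list was 3299 and 2444 CPM. In the heart list 11 of 17 rose (camera adjusted p = 1.22e-14, adjusted p = 0.578 with an estimated correlation), with sums of 2075 and 3240 CPM. Foregut endoderm (6 of 15 higher, 0 lower, median 0.68) and BMP targets (9 of 18 higher, 0 lower, median 0.65) passed camera as higher (adjusted p = 0.498 and 0.578 with an estimated correlation). So did the early epiblast list (2 of 16 higher, median 0.62) and the head organizer list (3 of 19 higher, median 0.39), with adjusted p = 0.578 and 0.578 with an estimated correlation. The forebrain list passed camera as lower with 0 of 22 members passing (median log2 fold change -0.60, camera adjusted p = 0.00382, adjusted p = 0.578 with an estimated correlation, 0 higher and 0 lower over the list alone). Lower, too, were neural crest (1 of 18 lower, median -0.79), midbrain (1 of 14 lower, median -0.44) and neuronal differentiation (1 of 14 lower, median -0.45), with adjusted p = 0.578, 0.578 and 0.578 with an estimated correlation. These 10 lists passed with the preset correlation, 0 passed with an estimated one (smallest adjusted p = 0.101), and the remaining 24 lists did not pass camera.

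Genes called against wild type overlapped between the 2 genotypes. Of the 916 genes higher in heterozygous libraries 902 were also higher in mutant libraries, against 156 for independent lists of these sizes and at most 1 in 20 simulations of unchanged groups. Of the 81 lower ones 77 were lower in mutant libraries as well, against 11 for independent lists and at most 1 in the simulations. The simulated value leaves out all effects and the independent one the shared controls. The 2 wild-type libraries were not divided between the comparisons, so part of the excess may come from them.

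The third comparison asks what differs between 2 copies and 1 copy of the allele. By title 66 genes passed, 11 higher and 55 lower in mutant libraries, and 0 with the files as attached. Lphn1, the adhesion receptor gene now named Adgrl1 (chromosome 8, 83900105 to 83941954, plus strand), stood at 194 and 169 CPM in wild-type, 189 and 195 in heterozygous and 9.55 and 8.11 in mutant libraries. Its log2 fold change against heterozygous was -4.44 (SE 0.11, adjusted p = 0.000362). Fut10 (chromosome 8, 31187331 to 31261738, plus strand) stood at 36.3 and 37.7 CPM in heterozygous and 0.186 and 0.375 CPM in mutant libraries (-7.08, SE 0.21, adjusted p = 0.000468). Cntnap2 (chromosome 6, 45059357 to 47304213, plus strand) changed by -6.41 (SE 0.29) and Cecr6, now Tmem121b (chromosome 6, 120488939 to 120493807, minus strand), by -5.55 (SE 0.41). Agap2 (chromosome 10, 127075284 to 127093169, plus strand) changed by -4.23 (SE 0.27) and Plch1, a phospholipase C gene (chromosome 3, 63696234 to 63899472, minus strand), by -3.93 (SE 0.16). The largest increases were in Cfi, complement factor I, at 2.18 (SE 0.18), Spp2 at 2.07 (SE 0.21), and F2, prothrombin, at 1.49 (SE 0.18). Folr1 was at 1.28 (SE 0.11), Cldn7 at 0.73 (SE 0.09) and Lad1 at 0.65 (SE 0.07). The adjusted p of these 12 genes lay between 0.000362 and 0.04998.

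All 55 genes lower in mutant than in heterozygous libraries were also lower in mutant than in wild-type libraries, against 7.46 for independent lists and at most 1 in simulations of unchanged groups. The mutant libraries are shared by both comparisons, so genes low in them tend to pass both. The simulated value leaves out all effects and the independent one this sharing, so neither gives the overlap to expect. Of these 55, 7 passed in heterozygous against wild type, all lower, and the median log2 fold change was -0.19 in heterozygous and -1.69 in mutant against wild type. The following members were picked after their values were seen. Satb1, a chromatin organizer gene, changed by -2.83 in mutant against heterozygous, the membrane traffic genes Scamp1 and Eps15 by -3.11 and -2.11, the ephrin gene Efnb3 by -2.06 and Tet1, a 5-methylcytosine oxidase gene, by -1.89. The Notch pathway genes Notch3 (-1.80) and Rbpj (-0.75), the hedgehog target Gli1 (-2.24), the FGF feedback gene Spry1 (-1.31) and the neural genes Sox1 (-0.58), Map2 (-1.37) and Stmn2 (-0.98) were among them. By their Xist and Y-linked counts both mutant libraries were female and both heterozygous libraries male, so sex and genotype coincide here. Wild-type replicate 1 was male and replicate 2 female, and 3 of the 55 genes are on the X chromosome. With a term for high Xist counts 4 of the 55 passed, Cntnap2, Fut10, Lphn1 and Plch1. Without heterozygous replicate 2, mutant replicate 2 or mutant replicate 1, 11, 14 and 15 of the 55 passed. Scaling to the neural progenitor list gave 6958 higher and 149 lower genes in place of 11 and 55, with the median of all genes moved by 0.54, and DESeq2 gave 699 higher and 614 lower.

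**Figure D3:**
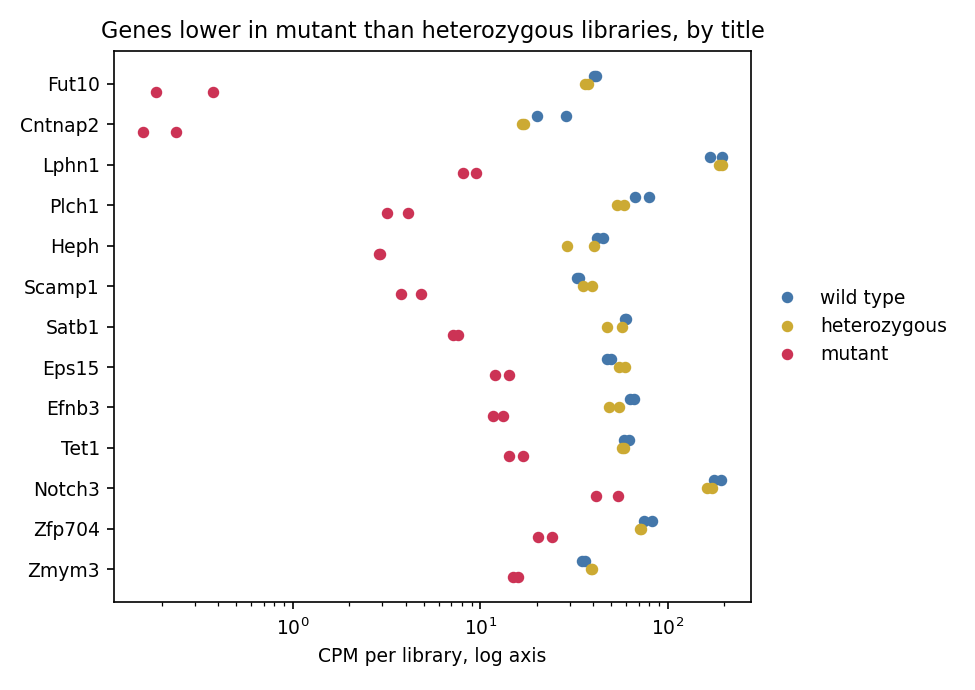
CPM (log axis) in each of the 6 libraries by title for the 13 genes lower in mutant than in heterozygous libraries that passed under at least 18 of 20 alternative settings, 2 points per genotype, a choice made after the values were seen. The 20 leave out the files as attached, where 0 of the 55 genes lower in mutant libraries passed, and the neural scaling, where 32 did. Each gene's mutant points lie below its wild-type and heterozygous points; Fut10 was below 0.4 CPM in both mutant libraries and above 36 CPM in the other 4.

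Over whole lists, mutant against heterozygous libraries had 17 lists past camera, 7 higher and 10 lower, and 0 past it with an estimated correlation (smallest adjusted p = 0.309). The forebrain list had 0 of 22 members passing over all genes (median log2 fold change -1.54, camera adjusted p = 1.45e-12, adjusted p = 0.309 with an estimated correlation, 0 higher and 15 lower over the list alone). The neural progenitor list had 1 of 17 lower over all genes and 7 lower over the list alone (median -0.51). Otx2 partners (median -1.34), neuronal differentiation (-0.83), midbrain (-0.66) and neural crest (-0.55) passed as lower, and BMP targets (0.33) and the early epiblast list (0.37) as higher. The immediate-early genes of dissection handling (median 0.31, camera adjusted p = 0.00282) passed as higher with these lists, and hypoxia and glycolysis (-0.20, camera adjusted p = 0.0257) as lower. Retinoic acid (0.55) and head mesenchyme genes (0.22) passed as higher, and hedgehog (-0.02) and sex-linked genes as lower. For all 17 lists the adjusted p lay between 0.309 and 0.615 with an estimated correlation. The yolk sac list had 0 of 18 passing over all genes and 16 higher over the list alone (median 1.03). The trunk list had 0 and 9 of 18 higher (median 2.14, 2.14 also with its member without heterozygous reads set at its bound). Notch pathway genes passed camera as lower, with 2 of 18 lower, a mean of -0.16 and a median of 0.08, of the other sign.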

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

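The alternatives fixed before the data were examined start from the files as attached; those that start from the libraries by title, and the Xist term, the neural scaling, the limma fit on the authors' RPKM and the fit without markers of 4 other tissues, were added after the result was seen. No paired analysis was possible because the libraries of the 3 genotypes share no replicate identity in their titles. Where single genes were followed, they were restricted to Prdm15, Otx2, the largest changes and members of lists that passed camera, and with the files as attached and under the neural scaling only Prdm15 and Otx2 were followed gene by gene. That restriction was made after many signs were seen to turn. Of the 78 genes picked for mutant against wild type 77 passed by title; as attached 0 did (smallest adjusted p = 0.99998), and 44 of the 77 had the other sign. Under the neural scaling 5 of the 77 changed sign.

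From the files as attached, where 0 genes passed, mutant against wild type had 4654 genes (2594 higher, 2060 lower) with the 2 files exchanged and 2046 (1465 and 581) without both. It had 86 with DESeq2, 114 with the likelihood ratio test, 66 with the exact test, and 0 to 1 on leaving out single libraries. Without both, wild type and mutant keep 1 library each and the spread comes from the heterozygous pair alone, so that fit replicates no difference between them. Heterozygous against wild type had 997 on exchange, 804 without both, 1 with each of DESeq2, the likelihood ratio and the exact test, and 0 to 1 on leaving out single libraries. Mutant against heterozygous had 66 on exchange, 180 without both, 98 with DESeq2, 140 with the likelihood ratio test, 165 with the exact test, 1 with only the 2 groups compared, and 0 to 1 on leaving out single libraries. The Otx2 log2 fold change in mutant against wild type went from -0.45 to -1.53 (adjusted p = 0.00964) on exchange and to -2.13 (adjusted p = 0.000317) without both libraries, again 1 library against 1. In that fit it was -0.57 (adjusted p = 0.0244) in heterozygous against wild type and -1.56 (adjusted p = 0.00269) in mutant against heterozygous. Leaving out single libraries it ranged from -1.60 to 0.37, from -0.57 to 0.78 and from -1.56 to 0.22 in the 3 contrasts.

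Gene lists passing camera with the files as attached numbered 10 in mutant against wild type, 9 in heterozygous against wild type and 8 in mutant against heterozygous. In the first contrast they were 21 without both conflicting libraries, 6 under the neural scaling and 6 to 17 on leaving out single libraries. In the second, leaving out single libraries gave 7 to 12. In the third they were 17 on exchange, 15 without both and 8 to 14 on leaving out single libraries. With an estimated correlation 0 lists passed in each contrast (smallest adjusted p = 0.919, 0.881 and 0.588), and with fry 0 in each (0.558, 0.977 and 0.251).

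From the libraries by title, the 4654 genes of mutant against wild type became 0 with the files as attached, 2046 without both conflicting libraries, 2500 with the Xist term and 11257 under the neural scaling, and ranged from 1997 to 4265 on leaving out single libraries (2459 and 3012 without wild-type replicates 1 and 2, 1997 and 2627 without mutant replicates 1 and 2). With library totals alone 46.2% of 5037 genes were higher, against 55.7% of 4654. The 997 genes of heterozygous against wild type became 0 with the files as attached, 1890 with DESeq2 (74.9% higher against 91.9%), 1579 with the likelihood ratio test and 516 with the Xist term. They ranged from 313 to 748 on leaving out single libraries (638 and 634 without wild-type replicates 1 and 2, 313 without heterozygous replicate 1). The 66 genes of mutant against heterozygous became 0 with the files as attached, 180 without both conflicting libraries, 182 with no low-count filter, 1313 with DESeq2, 801 with the likelihood ratio test, 1081 with the exact test, 106 with only the 2 groups compared, 4 with the Xist term and 7107 under the neural scaling. They ranged from 11 to 81 on leaving out single libraries (25 and 16 without mutant replicates 1 and 2, 11 without heterozygous replicate 2).

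By title Otx2 in mutant against wild type was -0.45 (adjusted p = 0.99998) with the files as attached and -1.96 to -1.21 on leaving out single libraries. Under the neural scaling Otx2 was -0.69 (adjusted p = 0.0357) there and -0.56 (adjusted p = 0.0945) in mutant against heterozygous. In heterozygous against wild type Otx2 was -0.57 (adjusted p = 0.0244) without both libraries. In mutant against heterozygous it passed without both libraries (-1.56, adjusted p = 0.00269), with DESeq2 (-1.11, adjusted p = 0.000237), the likelihood ratio test (-1.13, adjusted p = 0.00201) and the exact test (-1.13, adjusted p = 0.000525). The lists passing camera by title, 15, 10 and 17 in the 3 contrasts, became 0, 0 and 0 with an estimated correlation (smallest adjusted p = 0.227, 0.101 and 0.309). Fry passed 15, 2 and 0 lists. In mutant against wild type 12 of its 15 were among those past camera; hedgehog, surface ectoderm and the integrated stress response passed fry alone, and early epiblast, neural crest and Otx2 partners camera alone. With the files as attached the 17 became 8. On leaving out single libraries they ranged from 15 to 20, 11 to 13 and 13 to 17.

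Of 42 list results past camera by title, 17 had a median of the other sign with the files as attached, and 13 had the other camera direction. The medians as attached of those 13 were, in mutant against wild type, BMP targets (-0.25), canonical Wnt (0.12), foregut endoderm (0.039), heart (-0.90), Notch (0.069) and yolk sac visceral endoderm (-0.28). In heterozygous against wild type they were BMP targets (-0.10) and neuronal differentiation (-0.085), and in mutant against heterozygous BMP targets (-0.023), hedgehog (0.094), neural crest (0.36), yolk sac visceral endoderm (-0.12) and Notch (0.085), the last against a mean by title of -0.16. In foregut endoderm, the neuronal list of heterozygous against wild type and this Notch list the median kept its sign. The median alone turned in mutant against wild type for neural progenitor (-0.69 by title, 0.035 as attached), neural crest (-1.31, 0.11) and neuronal differentiation (-1.13, 0.014). It turned in heterozygous against wild type for yolk sac visceral endoderm (7.65, -0.19) and the early epiblast list (0.62, -0.017), and in mutant against heterozygous for midbrain (-0.66, 0.14) and neuronal differentiation (-0.83, 0.059). As attached, 11 of the 42 kept their camera pass and direction. So did 38 without both libraries, 40 with library totals and 35 under the neural scaling. Of 100 named-gene results by title none reversed in the settings where they were followed, which leave out the files as attached and the neural scaling; 85 still passed without both conflicting libraries, 82 with the Xist term, 95 with limma-voom, 98 with the authors' RPKM and 76 to 89 on leaving out single libraries.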

Other observations

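The tests in the closing paragraphs were chosen after the result was seen, except the permutation and location tests of the third pattern, which were written down before their values were computed.

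No gene passed edgeR's quasi-likelihood test with the files as attached (318, 48 and 422 at an unadjusted p under 0.05 in the 3 contrasts; DESeq2 86, 1 and 98, likelihood ratio test 114, 1 and 140, exact test 66, 1 and 165, limma-voom 0, 0 and 0), and the genes with the smallest p are given as values only. In mutant against wild type they were, with positive log2 fold changes, the granzyme genes Gzmg (5.71), Gzme (5.93) and Gzmf (5.60), Srgn, a proteoglycan gene of secretory granules (4.46), and A2m, a plasma protease inhibitor gene (5.12), with adjusted p from 0.277 to 0.604. Gzmg stood at 8.08 and 10.9 CPM in the pair of libraries titled wild-type replicate 2 and mutant replicate 2, and at most at 0.186 CPM in the other 4. A2m stood at 192 and 111 CPM in the same pair and at most at 5.03 CPM elsewhere. By title Gzmg and A2m did not pass in mutant against wild type (adjusted p = 0.882 and 0.774). Granzyme genes of this cluster are close paralogs, and reads may be shared among them. The smallest p with negative values were those of Pisd-ps1 (-0.96), Zfp932 (-0.98), Sez6 (-0.58), Ppme1 (-0.20) and Fzd8 (-0.36).

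Under the same assignment heterozygous against wild type had its smallest p at Mid1 (1.23), Ide (0.47), Erdr1 (0.84), Itga7 (1.24) and Smim22 (1.31), and with negative values at Banp (-0.67), Kcnq1ot1 (-0.74), Hoxd9 (-2.79), Hoxa9 and Psmb9. Hoxa9 and Psmb9 had 0 reads in both heterozygous libraries. In mutant against heterozygous the smallest p were those of Gzmg (6.32), Gzmf (6.22), Gzme (4.94), A2m (5.71) and Srgn (5.40), and with negative values of Mid1, Casq1 (-3.12), Pisd-ps1 (-0.86), Dnd1 (-1.44) and Ddx4 (-1.31).

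Primitive erythroid markers summed to 194 and 283 CPM in wild-type libraries, 29.7 and 266 CPM in heterozygous and 49.2 and 31.9 CPM in mutant libraries by title. The trunk and tailbud list summed to 54.3 and 22.4 CPM, 77.8 and 86.7 CPM, and 132 and 351 CPM. Sox10 was at 4.35 and 48.8 CPM and Tfap2b at 3.03 and 23.2 CPM in the heterozygous libraries, a spread between replicates that the erythroid sums share in direction, and neither gene passed in heterozygous against wild type.

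Yolk sac visceral endoderm genes were high in every heterozygous and mutant library by title. One hypothesis is that yolk sac tissue was carried into those dissections; it predicts that the list moves as a block between mutant and heterozygous libraries, and the members' log2 ratios there had an SD of 0.313 around a median of 1.03. Primitive erythroid genes, which yolk sac blood islands express, had a median of -2.01 in mutant against wild type, with 1 of 11 passing. In heterozygous against wild type it was -0.27, with 0 passing. Their sums did not track the yolk sac sums. They were 194 and 283 CPM in wild-type libraries, where the yolk sac sums were 146 and 143, and 266 CPM in heterozygous replicate 2. The erythroid list therefore decides nothing, and the values cannot tell on this hypothesis. A lower share of neural tissue alone predicts equal rises of other non-neural lists and is excluded, since the list's median lay 8.35 above that of endothelium (0.19). An effect of the allele inside head tissue predicts a rise in heterozygous libraries, and so does carried tissue; the median of 7.65 there cannot tell them apart.

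Forebrain genes were low in mutant libraries by title. Dilution of neural tissue predicts falls like those of neural progenitor genes. Their median was -0.64 without Pax6, which both lists hold. The forebrain median lay further down by a difference of -1.77 (permutation over genes, which are not independent, p = 0.00081). That argues against an even dilution of all neural tissue as the whole cause. The progenitor list is pan-neural, so the test cannot tell on a larger share of more caudal neural tissue. The hindbrain median was 1.01 (5 higher and 3 lower of 16). Sex as the whole cause predicts a median near 0 once a term for high Xist counts, set by 1 wild-type library of each sex, is in the model; it was -1.97 with the term (median SE 0.54, 10 of 22 passing) and -2.37 without it (18 passing). A loss of forebrain identity remains a hypothesis that fits the -1.77 and the -1.97, and so would a dissection that took less of the forebrain.

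The 55 genes lower in mutant than in heterozygous libraries form the third pattern. With the Xist term, which 1 male and 1 female wild-type library set, their median was -1.16, against -1.31 without it, and 4 passed as the median SE rose from 0.109 to 0.185. Their median lay below that of neural progenitor genes (-0.50) by a difference of -0.81 (permutation over genes, p = 0.0191), and scaled to the progenitor list 32 of the 55 passed as lower, with a median of -0.75. These values cannot tell on sex or dilution, because the genes were picked as lower in the same contrast. Sex as the whole cause predicts a like fall from the male to the female wild-type library. Over the 55 genes the median of that difference was -0.028 on the log2 scale. The pick favoured a small value, because this difference enters the spread of the shared fit behind each p-value. The median also rests on 1 library of each sex, so it cannot tell on sex. Dilution and sex stay open. Linkage to the targeted allele predicts genes near Prdm15. Of the 55, 0 lay within 20 Mb of it, where 0.564% of tested genes lie (one-sided Fisher's exact test, p = 1). With 0 genes there the p-value is fixed, so the test adds nothing to that count. The count covers that distance only.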
